A study of Rattus norvegicus with 24 samples.

How the data were processed

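RNA was profiled by sequencing in 24 libraries of rat cortical cells, grouped by 4 treatments (DMSO, IS141, AH609 and AH236) and 2 media (fresh growth medium or glutamate medium), with 3 libraries in each of the 8 groups. Groups were taken from the sample titles, and the replicate number came from the title where it gave one. A pair of AH236 glutamate libraries carried the number 2, and the later of them is called replicate 3 here. Per the labels' protocols, RNA was extracted with the RNeasy Mini Kit and libraries were made with a directional NEBNext Ultra II kit. The labels give no dose or timing for IS141, AH609 and AH236 and do not say what they are. Nothing says that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

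The authors deposited 1 table of whole-number counts per gene for all libraries, with Ensembl rat gene IDs and no normalization. Per the submitters' processing notes, the tools were bcl2fastq, cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3, with the genome build Rnor_6.0. Their roles, the annotation release and the strand setting are not given in the sources used here. RSEM estimates counts, so the deposited whole numbers may be rounded estimates, and the counts of genes that share reads with near-identical copies or overlapping genes are uncertain. The table had 32754 gene rows, of which 25683 had at least 1 count in some library. Library totals ran from 22509400 to 35496447 counts. The sizes of change that could be recovered at these totals are given with the simulations.

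The files used here do not pair the gene IDs with symbols, and 0 IDs could be matched to a name. The 30 gene lists fixed before the data were examined, which held 653 genes, and the symbol part of the rule for named genes could therefore not be applied, and none of these lists gave a result. The rule was to name, among genes past the threshold with a mean of at least 1 log2 CPM and with the sign of the change in every component difference, those with the largest rise and fall. It was applied without symbols to glutamate against medium over all 4 treatments, and the 2 top IDs in each direction are printed. Checks of GC content and gene length were void, because no ID had a value.

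Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 8 groups, which left 15908 genes. TMM factors were computed, dispersions were estimated with the robust option, and the quasi-likelihood F test was used with 1 mean per group in a single fit of all 24 libraries. The 17 comparisons were glutamate against medium in each treatment and over all 4, each treatment against DMSO in each medium, the difference between the glutamate effects, and the treatments against one another over both media. P-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. The standard error beside a log2 fold change is the one that gives the test's p at that fold change. The common biological coefficient of variation was 7.49%. Group levels are given in CPM after TMM scaling, as mean ± SD with n = 3.

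In place of the fixed lists, gene groups were defined after the data had been seen. For each treatment, a glutamate-raised and a glutamate-lowered group were formed. They held genes called and at least 2-fold changed in the same direction in the glutamate comparisons of both other treatments. Neither that treatment's libraries nor the DMSO libraries were among those compared. All 24 libraries entered the shared fit, however, and so the filter, scaling and dispersions behind these calls. The gene groups were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. A preset correlation of 0.01 and an estimated correlation were used, with adjustment over 12 tests. A glutamate response score per library was the mean log2 CPM of the raised group minus that of the lowered group. Scores were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

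The fit was tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 of 15908 genes changed in IS141 against DMSO in medium. It recovered 25 of 50 genes changed 1.25-fold, 45 of 50 changed 1.5-fold, 49 of 50 changed 2-fold and 49 of 50 changed 4-fold, with 7 calls among the unchanged genes. The changed genes were drawn only from genes with an average above 1 log2 CPM, so recovery at lower levels was not tried. Each gene was drawn on its own with 1 dispersion for all 8 groups, so no simulated library stood apart as DMSO replicate 1 does. These rates may therefore not hold for comparisons with the DMSO libraries in medium. Comparisons that share the DMSO libraries were set beside 5 simulations of unchanged treatments, which have the same limit. The alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter except 1 count in some library, the groups compared alone, the title number as a block, and each library left out. Scaling by library totals alone and leaving DMSO replicate 1 out of comparisons that do not use it were added after the data had been seen. No library was left out of the comparisons themselves. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of at least 4.825 in every pair. Figures were drawn with matplotlib.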

Results

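The series measured the transcriptome of rat cortical cells in culture under glutamate exposure, in the setting of excitotoxicity, the injury of neurons by excess glutamate, the main excitatory transmitter of the brain. Cells were plated in 6-well dishes and kept for 8 days before the medium was exchanged for fresh growth medium or for medium with 250 μM glutamate, after which the wells were imaged for 4 h in a live-cell scanner. When the RNA was taken is not stated. Cultures were given DMSO, a common solvent that is the control here, or 1 of 3 agents known by the code names IS141, AH609 and AH236, with 3 libraries for each treatment and medium. The 24 libraries held between 22509400 and 35496447 counts. The series title speaks of kinases, but the table used here holds RNA counts alone.

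Glutamate was the largest source of difference between the libraries. The first principal component of log2 CPM carried 69.9% of the variance and separated all 12 glutamate libraries from all 12 medium libraries. The second carried 4.72% and set DMSO replicate 1 in medium, at a score of 48.0, apart from the 23 other libraries, which lay between -19.7 and 12.8. The correlation between replicates across genes was as low as 0.982 for pairs with DMSO replicate 1 and at least 0.99255 for all other pairs. Overlaps of called genes between treatments and between media were not repeated without this library.

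**Figure D1:**
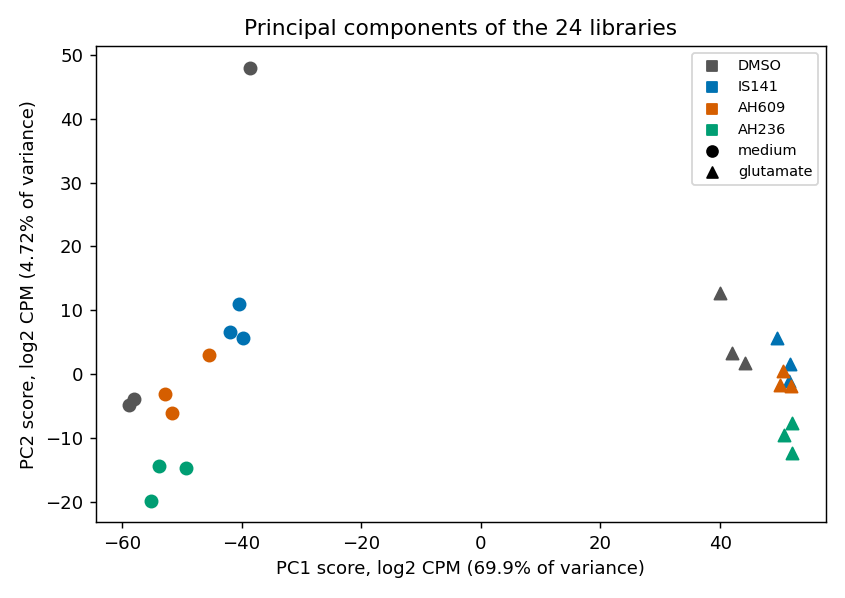
Principal component scores of the 24 libraries, from log2 CPM of 15908 genes, with PC1 on the x axis (69.9% of variance) and PC2 on the y axis (4.72%). Each point is 1 library, colour gives the treatment, circles are medium and triangles glutamate. The glutamate libraries lie at the right, and DMSO replicate 1 in medium lies alone at a PC2 score of 48.0.

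The first comparison asked how glutamate changed the transcriptome of DMSO-treated cultures. Of 15908 genes tested, 4548 were higher and 4859 lower in glutamate than in medium, which together were 59.1% of the genes. Most changes were small, and 78.3% of the called genes changed by less than 2-fold. At least 2-fold, 1268 genes rose and 771 fell, at least 4-fold 407 rose and 51 fell, and at least 8-fold 158 rose and 5 fell. Without DMSO replicate 1, 4695 genes were higher and 4939 lower, with 1443 rises and 750 falls of at least 2-fold. Genes that rose with glutamate over all 4 treatments took 53.3% ± 0.255 (SD, n = 3) of the counts of DMSO libraries in medium and 63.8% ± 0.755 (SD, n = 3) in glutamate. Genes that fell took 29.9% ± 0.377 (SD, n = 3) and 20.8% ± 0.476 (SD, n = 3). These shares describe genes chosen on the same libraries. Fold changes are relative to TMM scaling. Scaling by library totals alone, an alternative added after the data had been seen, moved the median log2 fold change of all genes from -0.01 to -0.20, and then 2882 genes were higher and 6948 lower, with 1002 rises and 1312 falls of at least 2-fold. Rises of at least 2-fold stayed more numerous with RLE size factors (1291 rises and 739 falls) and with DESeq2 (1253 and 721). Whether rises or falls were more numerous therefore depended on the scaling, but of the scalings tried only library totals turned the order.

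The same comparison was made in cultures given each agent, with libraries that no other single-treatment glutamate comparison shares. In IS141 cultures 4593 genes were higher and 4815 lower in glutamate, in AH609 cultures 4782 were higher and 4970 lower, and in AH236 cultures 4689 were higher and 4959 lower. Rises of at least 2-fold numbered 1282, 1488 and 1461 in the same order, and falls of at least 2-fold 833, 936 and 974. This excess of rises was also turned round by scaling to library totals, with 1000 rises and 1382 falls for IS141, 1204 and 1399 for AH609, and 1133 and 1614 for AH236. It stayed with RLE size factors, at 1304 and 809, 1514 and 909, and 1481 and 933 in the same order. The genes were largely shared. In all 4 treatments 3490 genes were called higher, where independent lists of these lengths would share 116, and 3711 were called lower, where independent lists would share 143. Opposite calls in different treatments were found for 46 genes. Across genes, which are not independent replicates, the log2 fold changes of any 2 treatments correlated with a Pearson r between 0.885 and 0.926. Over all 4 treatments 6166 genes were higher and 6300 lower in glutamate, and 4073 and 8586 under scaling by library totals.

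Among genes with a mean of at least 1 log2 CPM over the 24 libraries and the same direction in all 4 treatments, the largest rise belonged to ENSRNOG00000046667, which had a log2 fold change of 7.43 ± 0.22 (SE) over all 4 treatments (edgeR adjusted p = 1.68e-15). In DMSO cultures its level was 4.73 ± 5.16 CPM (SD, n = 3) in medium and 725 ± 68.7 CPM (SD, n = 3) in glutamate. The wide spread in medium came with DMSO replicate 1, and the log2 fold change in DMSO cultures was 7.26 with that library and 8.69 without it. The gene ENSRNOG00000020009 followed with 6.66 ± 0.11 (SE; adjusted p = 8.21e-20), and went from 8.37 ± 2.43 CPM (SD, n = 3) to 1247 ± 104 CPM (SD, n = 3) in DMSO cultures. The largest fall among these genes belonged to ENSRNOG00000033026, at -2.82 ± 0.08 (SE; adjusted p = 1.42e-21), with 10.4 ± 1.74 CPM (SD, n = 3) in medium and 1.20 ± 0.0942 CPM (SD, n = 3) in glutamate in DMSO cultures. ENSRNOG00000007332 fell by 2.62 ± 0.09 on the log2 scale (SE; adjusted p = 5.77e-19), from 7.33 ± 1.71 CPM (SD, n = 3) to 1.253 ± 0.15 CPM (SD, n = 3). Some genes with a lower mean rose or fell by more. The files pair no ID with a gene name, so what these genes encode is not stated.

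**Figure D2:**
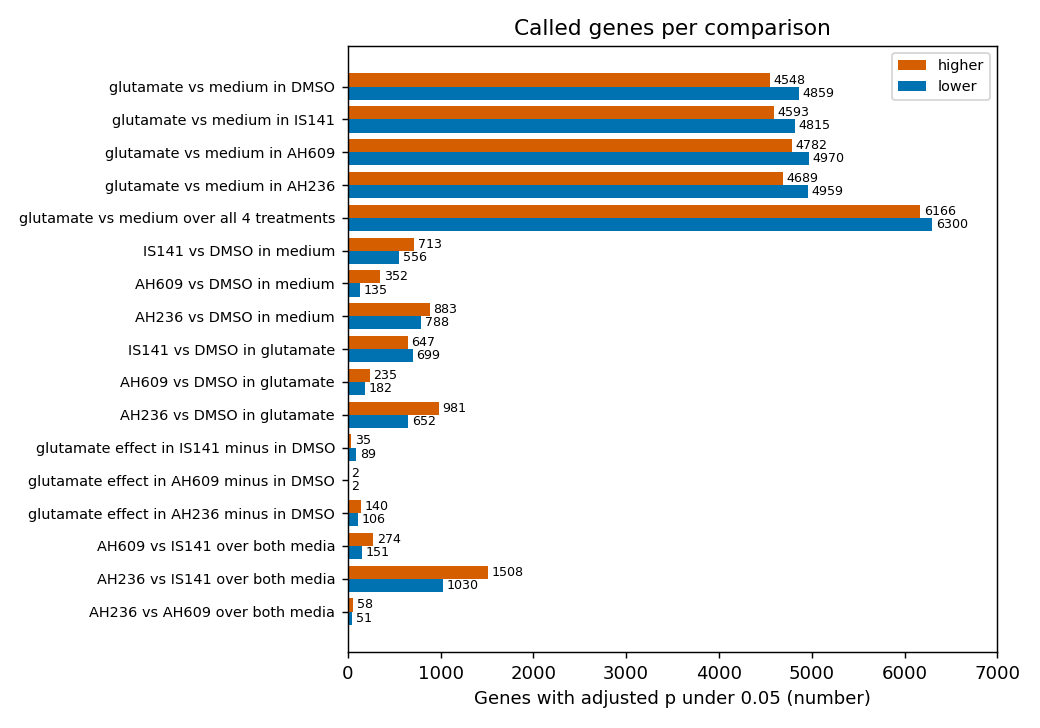
Number of genes called at an adjusted p under 0.05 (x axis) in each of the 17 comparisons (y axis), higher in orange and lower in blue. The glutamate comparisons call 4548 to 6300 genes in each direction, and the comparisons between treatments at most 1508.

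Each agent was then compared with DMSO in medium. With IS141, 713 genes were higher and 556 lower. With AH609, 352 were higher and 135 lower. With AH236, 883 were higher and 788 lower. Under scaling by library totals 657 were higher and 573 lower with IS141, but the direction turned for AH609, at 224 and 250, and for AH236, at 548 and 1419. Nearly all of these changes were small, and 94.1%, 93.8% and 90.5% of the called genes changed by less than 2-fold. Falls of at least 2-fold numbered 14 with IS141, 15 with AH609 and 137 with AH236, and rises 61, 15 and 22. These counts depended on single libraries. There were 13, 18 and 39 falls and 228, 96 and 49 rises without DMSO replicate 1. Without DMSO replicate 2 there were 31, 56 and 276 falls, and without DMSO replicate 3 45, 57 and 284. With any 1 of the 6 compared libraries left out, falls ranged from 7 to 45 for IS141, from 3 to 57 for AH609 and from 39 to 284 for AH236, and rises from 35 to 228, from 9 to 96 and from 20 to 49. Fits of the compared groups alone gave 0, 0 and 3 falls and 5, 0 and 3 rises. The gene ENSRNOG00000020009, which glutamate raised, was also higher with IS141 in medium, at 35.5 ± 6.60 CPM (SD, n = 3) against 8.37 ± 2.43 CPM (SD, n = 3) in DMSO, a log2 fold change of 2.08 ± 0.19 (SE; edgeR adjusted p = 4.46e-06), or 2.35 without DMSO replicate 1.

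Genes that glutamate had raised in the AH609 and AH236 cultures were higher with IS141 than in the mean of the DMSO libraries in medium, although they were lower than in DMSO replicate 1 alone (mean log2 difference -0.17). The mean log2 difference of these 1199 genes was 0.22, with 175 called higher and 13 lower (camera adjusted p = 9.04e-12), but the call was lost with an estimated correlation (adjusted p = 0.147). Without DMSO replicate 1 the mean was 0.41 and the call held with an estimated correlation (adjusted p = 0.000708). The 700 genes that glutamate had lowered were lower with IS141, by a mean of -0.11, with 11 called higher and 59 lower (camera adjusted p = 5.01e-08, and 0.00537 with an estimated correlation). With AH609 the 1052 raised genes had a mean difference of 0.04 (camera adjusted p = 0.0287, and 0.595 with an estimated correlation), and 0.23 without DMSO replicate 1 (adjusted p = 0.0141 with an estimated correlation). The 607 genes lowered had a mean of -0.03 (adjusted p = 0.0421, and 0.232 with an estimated correlation). With AH236 the 1135 raised genes had a mean of -0.09 (adjusted p = 0.576), with 73 called higher and 81 lower, and a mean of 0.09 without DMSO replicate 1 (adjusted p = 0.00147, and 0.197 with an estimated correlation). The 629 genes lowered had a mean of -0.11, with 6 called higher and 48 lower (camera adjusted p = 0.000188, and 0.0804 with an estimated correlation).

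When the compared groups were fitted alone, 62 genes were called in medium with IS141, 3 with AH609 and 87 with AH236, while in glutamate such fits called 1323, 580 and 1806. For IS141 the count was 1933 without DMSO replicate 1, 563 without IS141 replicate 2 and 798 without IS141 replicate 3. For AH609 it was 1003 without DMSO replicate 1, 223 without AH609 replicate 1, 250 without AH609 replicate 2 and 244 without AH609 replicate 3. For AH236 it was 934 without AH236 replicate 1 and 1048 without AH236 replicate 3.

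In glutamate, where the question was whether an agent altered the transcriptome of exposed cultures, 647 genes were higher and 699 lower with IS141 than with DMSO. With AH609, 235 were higher and 182 lower, and with AH236, 981 were higher and 652 lower. Scaling by library totals turned both of these splits, to 173 higher and 275 lower for AH609 and 425 and 1435 for AH236. It gave 499 and 860 for IS141. The IS141 split turned to 753 and 570 with the compared groups alone, 586 and 490 with no filter, and 767 and 747 with DESeq2. Its direction held with RLE size factors (652 and 655) and with the title number as a block (648 and 672). Changes of at least 2-fold were few, with 29 rises and 23 falls for IS141, 8 rises and 12 falls for AH609, and 12 rises and 31 falls for AH236. With DMSO replicate 1 left out of the shared fit there were 48 rises and 31 falls for IS141, 17 and 15 for AH609, and 17 and 63 for AH236. With any 1 of the 6 compared libraries left out, rises ranged from 16 to 29, from 3 to 5 and from 7 to 14, and falls from 16 to 28, from 4 to 13 and from 24 to 33. DESeq2 gave 6 rises and 11 falls for IS141, 0 and 6 for AH609, and 5 and 14 for AH236, and scaling by library totals gave 9 rises and 54 falls for AH236. Genes that glutamate had lowered in the other agents' cultures were lower still with each agent. Their mean log2 difference from DMSO was -0.17 with IS141 (85 called lower and 3 higher), -0.19 with AH609 (34 called lower and 0 higher) and -0.26 with AH236 (126 called lower and 5 higher). The camera adjusted p-values were 7.9e-11, 3.85e-16 and 3.48e-19, and 0.00154, 0.000232 and 0.000232 with an estimated correlation. Genes that glutamate had raised were higher, with mean differences of 0.13, 0.15 and 0.12 and 98, 49 and 183 members called higher, against 12, 0 and 8 called lower (camera adjusted p = 8.06e-07, 7.02e-11 and 3.74e-08). These calls were lost with an estimated correlation (adjusted p = 0.232, 0.147 and 0.17). Without DMSO replicate 1 the estimated correlations were lower, and the adjusted p-values with them were 0.0515, 0.017 and 0.0362.

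The glutamate response score put these differences on 1 scale per library. In glutamate it was 2.05 ± 0.0475 (SD, n = 3) with IS141 against 1.74 ± 0.0798 (SD, n = 3) in DMSO, 2.19 ± 0.0346 against 1.85 ± 0.0757 for AH609, and 1.94 ± 0.0103 against 1.55 ± 0.0753 for AH236. All 3 libraries of each agent lay above all 3 DMSO libraries, and each exact permutation test gave p = 0.1, the smallest possible with 3 against 3 libraries (two-sided; 0.2 after adjustment over 6 tests). The 3 tests share the same DMSO libraries. In medium the score was -0.93 ± 0.0412 with IS141 against -1.26 ± 0.333 in DMSO (exact permutation p = 0.4), and the DMSO mean was -1.45 without replicate 1. With AH609 and AH236 the exact permutation p-values in medium were 0.7 and 1. The difference between glutamate and medium was 2.98 ± 0.0363 (SE) with IS141, which was 99.3% of that in DMSO. It was 3.40 ± 0.0634 (SE) with AH609, or 109% of that in DMSO, and 3.41 ± 0.0502 (SE) with AH236, or 112%. Without DMSO replicate 1 these shares were 93.4%, 103% and 106%. The difference from DMSO was -0.02 ± 0.201 (SE) for IS141, 0.28 ± 0.202 (SE) for AH609 and 0.36 ± 0.180 (SE) for AH236. These differences were -0.21, 0.09 and 0.19 without DMSO replicate 1.

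**Figure D3:**
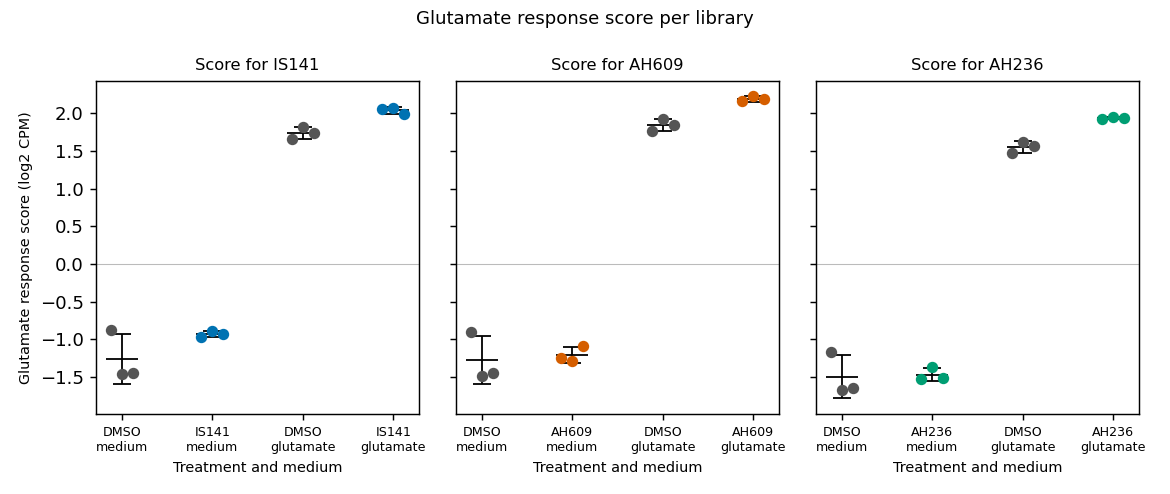
Glutamate response score (y axis, mean log2 CPM of glutamate-raised minus glutamate-lowered genes) by treatment and medium (x axis), with 1 panel for each agent and its own gene groups. Points are libraries, the horizontal bar is the mean and the error bar the SD of 3 libraries. In glutamate the libraries of each agent lie above the DMSO libraries, for example at 1.93 to 1.95 against 1.47 to 1.62 for AH236.

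Single libraries also moved the counts in glutamate. Leaving DMSO replicate 1 out of the shared fit raised them to 2423 for IS141, 995 for AH609 and 2530 for AH236. For IS141 the count was 605 without DMSO glutamate replicate 1, 656 without DMSO glutamate replicate 2, 632 without IS141 glutamate replicate 1 and 661 without IS141 glutamate replicate 2. For AH609 it lay between 163 and 274 with any 1 of the 6 compared libraries left out. For AH236 it was 801 without DMSO glutamate replicate 1, 966 without AH236 glutamate replicate 1 and 876 without AH236 glutamate replicate 3.

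Effects of the agents in medium and in glutamate, which share no library, were compared next. Of the genes called with IS141 in both media, 229 were higher in both, where independent lists would share 29.0, and 153 lower in both, where they would share 24.4, while 8 had opposite signs. With AH609, 102 were higher in both (5.20 by independent lists) and 28 lower (1.54), and 1 was opposite. With AH236, 359 were higher in both (54.4 by independent lists) and 129 lower (32.3), and 20 were opposite. Such excesses were not particular to an agent. Between different agents, IS141 in medium shared 105 higher genes with AH609 in glutamate (10.5 by independent lists) and 195 with AH236 in glutamate (44.0), AH609 in medium shared 138 with IS141 (14.3) and 154 with AH236 (21.7), and AH236 in medium shared 207 with IS141 (35.9) and 132 with AH609 (13.04). In the same order the genes lower in both numbered 50, 87, 32, 34, 92 and 65 (6.36, 22.8, 5.93, 5.53, 34.6 and 9.02 by independent lists), and those with opposite signs 2, 40, 3, 10, 23 and 5. Across genes the log2 fold changes of the same agent in the 2 media correlated with r = 0.272 for IS141, 0.147 for AH609 and 0.237 for AH236. Between different agents in different media r lay between 0.0984 and 0.205.

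Within a medium the agents share the DMSO libraries, so their fold changes correlate by design. In medium r was 0.636 for IS141 and AH609, 0.532 for IS141 and AH236, and 0.711 for AH609 and AH236, against means of 0.467, 0.502 and 0.478 in simulations of unchanged treatments. The observed r was 0.736, 0.574 and 0.675 without DMSO replicate 1, and the simulations were not repeated without it. The covariances were 0.0653, 0.0658 and 0.0875, against 0.029, 0.0301 and 0.0293 in the simulations. In glutamate r was 0.623, 0.455 and 0.572 for the same pairs, against 0.469, 0.468 and 0.474, and the covariances were 0.0478, 0.0391 and 0.0461, against 0.0253, 0.0258 and 0.026. Shared calls of the same sign in medium numbered 325, 474 and 413 for these pairs. By direction, 254, 310 and 300 were higher in both, and 71, 164 and 113 were lower in both. In glutamate the shared calls numbered 319, 452 and 296. Of these, 185, 252 and 177 were higher in both, and 134, 200 and 119 were lower in both. In the simulations the highest number of shared calls was 0 for every pair. No simulated library stood apart as DMSO replicate 1 does, which also limits the simulated r and covariances. The 3 DMSO libraries of a medium are too few to be split. How many shared calls come from the shared controls was therefore not measured in the real libraries.

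Whether an agent changed the effect of glutamate was tested as the difference between the glutamate effect with the agent and that with DMSO. The counts were not beyond those of other splits of the libraries, but such splits cannot measure chance for this difference. Treatments were exchanged separately in each medium. A split that exchanges them in 1 medium alone turns the agent's difference from DMSO into a difference between glutamate effects. With treatments exchanged within each medium, at least as many genes were called in 10 of 100 drawn splits for IS141, 18 of 100 for AH609 and 9 of 100 for AH236, the real split included, and other splits called up to 1591, 766 and 1054 genes. With IS141, 35 genes had a more positive and 89 a more negative glutamate effect than with DMSO. Of the 35 genes, 8 were raised and 20 lowered by glutamate in DMSO cultures. With IS141, 16 of them were called lower in medium and 24 higher in glutamate. Of the 89 genes, 65 were raised by glutamate in DMSO cultures, 61 were called higher with IS141 in medium and 29 were called lower with IS141 in glutamate. The gene ENSRNOG00000020009 was among them, with a difference of -1.82 ± 0.25 on the log2 scale (SE; edgeR adjusted p = 0.0014). With AH609, 2 genes had a more positive and 2 a more negative effect, and 1151 genes had an unadjusted p under 0.05. With AH236, 140 genes had a more positive and 106 a more negative effect. Of the 140 genes, 90 were raised by glutamate in DMSO cultures, 75 were called lower with AH236 in medium and 78 higher in glutamate. Of the 106 genes, 37 were raised and 53 lowered by glutamate in DMSO cultures. With AH236, 54 of them were called higher in medium and 51 lower in glutamate. For both agents the genes were chosen on a difference between the same group means that these breakdowns use. The breakdowns are therefore partly fixed by that choice. Without DMSO replicate 1 the counts were 201 more positive and 541 more negative with IS141, 35 and 179 with AH609, and 234 and 262 with AH236. Scaling by library totals gave 23 and 99 with IS141, 1 and 2 with AH609, and 105 and 105 with AH236. Fitted with the compared groups alone, the totals were 30, 0 and 18, and DESeq2 called 208, 28 and 429. In the fit of the compared groups alone that called 0 genes for AH609, 813 genes had an unadjusted p under 0.05.

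Other libraries moved these totals as well. For IS141 the total was 71 without DMSO glutamate replicate 2, 82 without IS141 replicate 2, 68 without IS141 glutamate replicate 2 and 72 without IS141 glutamate replicate 3. For AH609 it was 7 without DMSO replicate 2 or without DMSO glutamate replicate 3, 10 without AH609 replicate 2, 1 without AH609 replicate 3, 9 without AH609 glutamate replicate 2 and 0 without AH609 glutamate replicate 3, where 1002 genes had an unadjusted p under 0.05. For AH236 it was 487 without DMSO replicate 2, 385 without DMSO replicate 3, 77 without DMSO glutamate replicate 1 and 163 without DMSO glutamate replicate 2, and it lay between 82 and 141 with any 1 AH236 library left out.

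The agents were compared with one another over both media, without the DMSO libraries. AH236 and IS141 differed most, with 1508 genes higher and 1030 lower with AH236, of which 6 rose and 64 fell at least 2-fold. Between AH609 and IS141, 274 genes were higher and 151 lower with AH609. Between AH236 and AH609, 58 genes were higher and 51 lower with AH236, and 3 of these fell at least 2-fold. With DMSO replicate 1 left out of the shared fit, 8 genes rose and 102 fell at least 2-fold for AH236 against IS141, and 1 rose and 14 fell for AH236 against AH609. With any 1 of the compared libraries left out, falls of at least 2-fold ranged from 50 to 83 and from 0 to 1. The majority turned in all 3 comparisons under scaling by library totals, with 725 genes higher and 2024 lower for AH236 against IS141, 142 and 213 for AH609 against IS141, and 29 and 98 for AH236 against AH609. Doses are not stated, so these differences are not at known matched doses. On a glutamate response score from the 1268 genes raised and 771 genes lowered at least 2-fold in DMSO cultures, AH609 and AH236 in medium differed by 0.01 (95% interval -0.19 to 0.21, exact permutation p = 0.9). IS141 in medium lay above AH609 and above AH236, and AH609 minus IS141 was -0.25 (95% interval -0.44 to -0.07) and AH236 minus IS141 was -0.24 (95% interval -0.41 to -0.07), with an exact permutation p = 0.1 for each, the smallest possible, and 0.3 after adjustment over 6 tests. In glutamate the differences were 0.00 (95% interval -0.11 to 0.12) for AH609 minus IS141, 0.07 (95% interval -0.05 to 0.18) for AH236 minus IS141 and 0.07 (95% interval -0.02 to 0.15) for AH236 minus AH609 (exact permutation p = 0.9, 0.2 and 0.2).

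The counts between agents were higher when DMSO replicate 1 was left out of the shared fit, at 1374 for AH609 against IS141, 3651 for AH236 against IS141 and 641 for AH236 against AH609. Fitted with the compared groups alone they were 1753, 3629 and 793, and DESeq2 called 727, 2593 and 241. For AH609 against IS141 the count was 107 without IS141 replicate 2, 265 without IS141 replicate 3, 124 without IS141 glutamate replicate 1, 167 without IS141 glutamate replicate 2, 269 without AH609 replicate 1, 92 without AH609 replicate 2, 254 without AH609 replicate 3, 95 without AH609 glutamate replicate 1 and 135 without AH609 glutamate replicate 2. For AH236 against AH609 it lay between 41 and 64 with any 1 of the compared libraries left out but AH236 replicate 2. With the title number as a replicate block it was 64, with 0 falls of at least 2-fold.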

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

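The tests of mixed RNA in DMSO replicate 1, of an exchanged label, of a shared culture state, of 1 library setting the score difference and of 1 DMSO library setting the IS141 difference, with each DMSO library left out or as the only reference, were chosen after the results had been seen. The tests of mixed RNA in the IS141 libraries, of depth and of other splits were written down before their values were seen.

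The glutamate effect differed between treatments by a test of the difference itself. This held for 124 genes with IS141, 4 genes with AH609 and 246 genes with AH236, each against DMSO. Splits in which treatments were exchanged within each medium gave at least as many genes in 10 of 100 drawn splits for IS141, in 18 of 100 for AH609 and in 9 of 100 for AH236, the real split included. The highest counts among the other splits were 1591, 766 and 1054. These splits cannot measure chance here, because exchanging treatments in 1 medium alone turns an agent's difference from DMSO into a difference between glutamate effects. Chance is not excluded for these counts. ENSRNOG00000020009, the gene named for IS141, kept its call in every alternative fit that was run (adjusted p from 2.24e-07 to 0.0324). Whether the splits with several times the real count come near an exchange in 1 medium alone was not tested. The totals were 742, 214 and 496 without DMSO replicate 1.

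DMSO replicate 1 in medium was 1.5-fold or more above all 23 other libraries in 65 genes and below all of them in 34, where no other library reached more than 8 in either direction. Among 242 genes at least 2-fold higher in it than in DMSO replicates 2 and 3, 136 were also raised at least 2-fold by glutamate in the cultures of each agent. RNA from glutamate-exposed cultures mixed into this library would move strongly raised genes by about 1 common share of their glutamate shift, but over 197 genes raised at least 8-fold the interquartile range of the shares was 17.05 percentage points (from 2.02% to 19.1%), against 1.99 points between DMSO replicates 2 and 3. The ratio of the median share in strongly to that in weakly raised genes, 0.738 (95% bootstrap interval over genes 0.555 to 1.11), did not by itself argue against mixing. A label exchanged with a glutamate library is argued against by its glutamate response score of -0.875, since the lowest glutamate library had 1.66. The score cannot tell an exchange with another medium library, as IS141 libraries in medium scored -0.975 to -0.893. An exchange alone would place the library among those of another group. Its PC2 score of 48.0 lay outside the range of the 23 other libraries, -19.7 to 12.8. That argues against an exchange within medium as the reason it stands apart. A culture state shared with DMSO glutamate replicate 1 was not supported by the test chosen for it. The median deviation of the 242 genes there, 0.0493, was not above those of all libraries of the agents, which reached 0.249, as such a state would need. The value was not at or under 0 either, the bound set for arguing against it. On PC2, DMSO glutamate replicate 1 scored 12.8, the highest of the 23 other libraries. Its deviations from its group mean correlated across genes with those of DMSO replicate 1 at r = 0.131. For DMSO replicate 3 and DMSO glutamate replicate 3 r was 0.169, so such a value was not particular to DMSO replicate 1. A shared culture state stays open.

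Each agent lay above DMSO on the glutamate response score in glutamate, by 0.31 to 0.39. After all libraries had been thinned to 22509400 counts the smallest difference was 0.3135, above the larger SD of the groups (0.0801 for IS141), which argues against depth as the cause. With any 1 library left out the smallest difference was 0.2673, against an SD of 0.0798 for IS141. That outcome was fixed in advance, because the lowest library of each agent lay above the highest DMSO library by more than the larger SD (1.99 and 1.82 for IS141). The separation itself argues against a single library as the cause, and the test adds nothing to it. The tests share the DMSO libraries and cannot give a p under 0.1, so chance and an unrecorded difference in handling between the DMSO and the agent cultures stay open. A response to the agents may also account for it, as an untested hypothesis.

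IS141 in medium lay above the mean of the DMSO libraries in genes that glutamate had raised in other cultures, but not above each of them. The glutamate response score of DMSO replicate 1, -0.875, was above those of all 3 IS141 libraries (-0.975 to -0.893), the exact permutation p was 0.4, and the call of the gene group was lost with an estimated correlation (adjusted p = 0.147). Mixed-in RNA from glutamate-exposed cultures is argued against, because the share of the glutamate shift was 4.72% in genes raised at least 8-fold and 8.81% in genes raised 2-fold to 4-fold, a ratio of 0.5355 (95% bootstrap interval 0.441 to 0.6) against DMSO replicates 2 and 3 and of 0.303 (0.189 to 0.389) against all DMSO libraries. These intervals resample genes, not libraries, so they leave out the spread between libraries. The mean log2 difference of the raised genes was 0.4124 without DMSO replicate 1, 0.1188 without replicate 2 and 0.1214 without replicate 3, against an SD of 0.3375 between the DMSO libraries. With 1 DMSO library as the only reference it was -0.1722 for replicate 1, 0.4149 for replicate 2 and 0.4098 for replicate 3, so both its size and its sign depended on the reference. Whether 1 DMSO library sets the difference stays open, as do an effect of IS141 and differences in handling between cultures.

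For the glutamate comparisons within a treatment and the comparisons of an agent with DMSO in 1 medium, the 10 splits of 6 libraries are too few for a share under 0.05, and the real split gave the highest count in each (1 of 10). The real counts of 9407, 9408, 9752 and 9648 for glutamate in DMSO, IS141, AH609 and AH236 stood against 636, 0, 0 and 0 in the highest other split. For IS141, AH609 and AH236 against DMSO in medium the real counts of 1269, 487 and 1671 stood against 492, 377 and 85, and in glutamate the counts of 1346, 417 and 1633 stood against 0, 0 and 0. For glutamate over all 4 treatments the real split gave 12466 genes, against 9456 in the highest of 99 other drawn splits. Between agents over both media it gave 425 against 8 for AH609 and IS141 and 2538 against 562 for AH236 and IS141. For AH236 and AH609 it gave 109 against 43. Each share, 1 of 100, argues against a chance arrangement of these libraries, without adjustment over the 17 comparisons. It cannot exclude differences between cultures or in handling.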

How the results depend on the processing

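Scaling by library totals and leaving DMSO replicate 1 out of fits that do not compare it were added after the data had been seen. Of 101 counts of called genes under another tool, scaling, filter or fit, 86 were within 1.5 times the reported count. The 22 fold changes of the 4 named IDs kept direction and call in all 350 alternatives. These IDs were chosen from the same libraries for their large glutamate changes, so this says little about smaller changes or the agents. With no filter, the AH609 difference in glutamate effect called 14 genes in place of 4. DESeq2 called 208, 28 and 429 genes for the IS141, AH609 and AH236 differences, 727 for AH609 against IS141 and 241 for AH236 against AH609. Fits of the compared groups alone called 62, 3 and 87 genes for IS141, AH609 and AH236 against DMSO in medium. Such fits called 30, 0 and 18 for the differences in glutamate effect, where 813 genes had an unadjusted p under 0.05 for AH609. They called 1753 for AH609 against IS141 and 793 for AH236 against AH609. In glutamate, fits of as many libraries called 1323, 580 and 1806 for IS141, AH609 and AH236 against DMSO. That argues against the smaller number of libraries alone as the cause of the low counts in medium. All counts that fell by over 1.5 times in such fits use the DMSO libraries in medium. Other causes of these shifts were not tested.

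Leaving out 1 library gave 563 to 1933 genes for IS141, 223 to 1003 for AH609 and 934 to 2229 for AH236 against DMSO in medium. In glutamate the ranges were 605 to 2423, 163 to 995 and 801 to 2530. For the differences in glutamate effect they were 68 to 742, 0 to 214 and 77 to 496, for AH609 against IS141 92 to 1374 and for AH236 against AH609 41 to 641. Of 165 such counts, 70 moved by over 1.5 times. The 5 glutamate comparisons were not among these.

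Scaling by library totals moved the split of higher against lower genes by over 10 percentage points in 14 of 17 comparisons. For glutamate it gave 2882 higher and 6948 lower in DMSO, 2854 and 7032 in IS141, 3245 and 6785 in AH609, 2971 and 7055 in AH236, and 4073 and 8586 over all 4. In medium it gave 224 and 250 for AH609 and 548 and 1419 for AH236. In glutamate it gave 499 and 860 for IS141, 173 and 275 for AH609 and 425 and 1435 for AH236. The AH609 difference had 1 and 2, and between agents the splits were 142 and 213 (AH609, IS141), 725 and 2024 (AH236, IS141) and 29 and 98 (AH236, AH609).

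With the title number as a replicate block, the count for AH236 against AH609 was 64 in place of 109 and no other count moved by over 1.5 times. The numbers are not shown to pair the samples. Deviations of same-numbered libraries correlated with r between -0.0806 and 0.169, over 0.1 in 2 of 12 pairs, and in 7 of 12 pairs the glutamate library of the number was the best partner. AH236 replicate 2 was in 2 pairs and AH236 replicate 3 in none. The set tests planned on the fixed gene lists were not run, because no list could be matched.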

Other observations

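The test in this part was chosen after the result had been seen. Genes that stood high in DMSO replicate 1 also differed between the agents, in comparisons that use no DMSO library. The 242 genes at least 2-fold higher in DMSO replicate 1 than in replicates 2 and 3 had a median log2 fold change of -0.45 for AH236 against IS141 over both media, with 53 called lower and 0 called higher. For AH609 against IS141 the median was -0.18 with 2 called lower and 0 higher, and for AH236 against AH609 it was -0.26 with 1 called lower and 0 higher. These calls come from the shared fit that keeps DMSO replicate 1. The deviation that chose the genes enters their dispersions there, so the calls may be too few. Camera with DMSO replicate 1 left out gave p = 1.22e-48 for AH236 against IS141, and p = 0.000474 with an estimated correlation (adjusted p = 0.00142 over the 3 comparisons). With an estimated correlation the adjusted p-values were 0.00935 for AH609 against IS141 and 0.00149 for AH236 against AH609. In the cultures of the agents these genes had a median log2 fold change with glutamate of 1.64. A hypothesis is that they form a set of genes that varies together across cultures, in which DMSO replicate 1 and the IS141 cultures may stand high and the AH236 cultures low.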
